A study of Triticum dicoccon x Aegilops tauschii subsp. strangulata and Triticum turgidum subsp. durum x Aegilops tauschii subsp. strangulata and Aegilops tauschii subsp. strangulata with 28 samples.

How the data were processed

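Total RNA of wheat seedlings was measured on Agilent 1-colour oligonucleotide arrays, 1 sample per array, after Cy3 labelling by linear amplification, per the labels' protocols. Each array holds 39243 spots, of which 37826 are non-control probes of 60 bases, each present once. For 281 probes the sequence is shared with another probe. The probes carry clone or contig names and no gene names, no gene table was given, and so the gene lists, cell type markers and list tests fixed before the data were examined could not be run. Probes are given by number, with the contig name for some.

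The scanner files hold intensities per spot, with background subtraction and spatial detrending by Agilent's Feature Extraction software, per the file headers. The normalized values deposited by the authors are on a log2 scale for 18248 probes. Set against the scanner files, they equal the log2 processed intensity minus the 75th percentile of the array and minus an offset per probe that is the same in all 28 columns, with a largest difference of 0.0039. Which offset was taken off and which filter chose the probes is not given in the sources used here, so levels of different probes in that table cannot be set against each other. Its column medians lay between -0.095 and 0.387. All of its probes (100%) were well above background on every array of at least 1 group, and 79.1% were so on all arrays.

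From the scanner files, the log2 processed intensity minus each array's 75th percentile was used as the level. Spots marked as non-uniform or as outliers by the software were left out, 0 to 591 per array, and saturated spots were kept. A probe was kept where it was well above background on every array of at least 1 of the 10 groups, which left 29706 probes. The number tested falls slightly below this where all spots of a group had been left out. Between 51.7% and 78.2% of probes were well above background per array. The replicates are described as biological in the series' design text.

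All 28 arrays were fitted together with limma 3.58.1 (lmFit and eBayes, in R 4.3.3), with a mean per group and a spread pooled over the 10 groups. Probes were called at an adjusted p (Benjamini-Hochberg) under 0.05. The mid-parent was the log2 of the equal-weight mean of the parents' linear levels, with its error from the pooled variance by the delta method. The difference of non-additivity is the cross 2 deviation from the mid-parent minus that of cross 1. Probes were named by a rule fixed before the data were examined, which asked for genes with names and, where probes have none, for at most 2 probe numbers that rose and 2 that fell in each of the parents, triploid, doubling and selfing comparisons. These were the probes with the largest log2 difference among called probes whose arrays did not overlap, and against the mid-parent those with every hybrid array on the same side of it. Non-overlap arises by chance in 10% of probes with 3 arrays against 3. Where a probe was not well above background on any array of a group, the fold is given as a lower bound, with the dim group at the mean, over its arrays, of the higher of the probe's own level and the lowest level among probes well above background. In a fall against the mid-parent, a dim parent was set to a contribution of 0. A level in the text is a log2 value relative to the array's 75th percentile.

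Alternatives were quantile normalization, normexp background correction (offset 50) of mean and local background intensities, the deposited matrix, no filter, a stricter filter (well above background in every group of the cross), a fit per cross, a mean-variance trend, slide as a fixed or random block, the replicate number as a block, each array left out in turn, 2:1 weights and a log2 mid-parent. After the data were seen, 4 further alternatives were added: a local surface (the median deviation of the 150 nearest probes) taken off each array, interior probes alone, hybrid arrays recentred on probes alike in the parents, and a block with the numbers of the cross 2 triploids crossed. Margin probes lie in rows up to 20, rows from 513 or columns from 79, of 532 rows and 85 columns, and interior probes in rows 41 to 450 and columns 4 to 60. The arrays came from 10 slides and 8 scan days, per the file headers. Same-numbered arrays of the parents shared a slide in both crosses, so the numbers pair the parental arrays by slide. Each parental array correlated best with its own number in cross 1 (6 of 6 arrays), but only 4 of 6 did in cross 2. The correlations of their deviations from the group means lay at r between 0.146 and 0.229 in cross 1 and between 0.152 and 0.403 in cross 2. For the tetraploid and the late hexaploid of cross 1 the range was 0.204 to 0.271. In the other pairs of groups compared at least 1 correlation was 0.1 or less. No column of another series was used (0 columns).

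The fit was tested on simulated data for 29637 probes, 200 of them changed. All groups, the parents included, had the same level at the other probes, and far fewer probes changed than were called in the real comparisons. The recovery and the false calls therefore hold for that setting and do not carry over to the real counts. For the parents of cross 1 it recovered 69.7% of 4-fold and 13.4% of 2-fold changes, with 3 false calls. For the triploid against the mid-parent of cross 1 it recovered 69.7% and 4.5%, with 1 false call. For chromosome doubling of cross 1 it recovered 40.9% and 6.0%, with 1 false call, and for selfing of cross 1 66.7% and 4.5%, with 3. Splits of the same arrays were refitted, all 10 for 3 arrays against 3 and 100 for comparisons with the mid-parent, with the real split counted in both. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.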

Results

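Gene expression was measured in seedlings during the formation of synthetic hexaploid wheat. A tetraploid wheat (genomes AABB) was the maternal parent and the wild diploid goat grass Aegilops tauschii subsp. strangulata (genome DD) the paternal parent. A triploid hybrid (ABD) arises first, its chromosomes are doubled to give the hexaploid (AABBDD), and the hexaploid is then selfed. In cross 1 the tetraploid was emmer wheat (Triticum dicoccon) and in cross 2 durum wheat (Triticum turgidum subsp. durum). Each cross was sampled as tetraploid parent, diploid parent, triploid, generation 1 hexaploid and a late hexaploid, which was generation 14 after 13 rounds of selfing in cross 1 and generation 5 after 4 rounds in cross 2. There were 28 arrays in 10 groups, with n = 2 for each triploid and n = 3 for each of the other groups, and this number of arrays limits the precision. The 75th percentile of intensity per array lay between 1157.5 and 1668.9 in the cross 1 triploids, between 1829.8 and 1975.3 in the cross 2 triploids and between 130.3 and 365.2 in the late hexaploids of cross 2. Replicate arrays of a group correlated across probes at r between 0.930 and 0.990. The lowest value was in the late hexaploids of cross 2, whose median replicate SD was 0.52 on the log2 scale, against 0.16 in the cross 2 triploids.

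The arrays of both parents and of the late hexaploid shared slides in each cross, whereas each triploid and each generation 1 group lay on a slide of its own. On the slides of the cross 2 parents and late hexaploids, probes near the array margin were dim. The median deviation of margin probes minus that of interior probes was -1.79 to -1.08 on the log2 scale in the late hexaploids of cross 2, -0.85 to -0.13 in their diploid parent and -0.68 to -0.11 in their tetraploid parent. On the arrays of the other 7 groups it lay between 0 and 0.25.

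**Figure D1:**
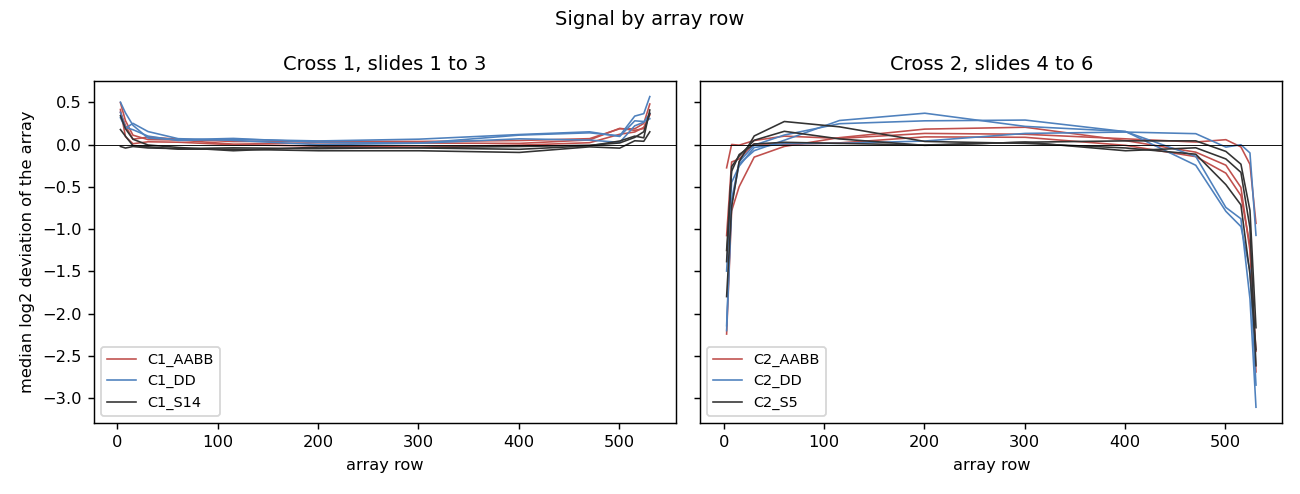
Median log2 deviation of each array (y axis) by array row (x axis), 1 line per array, for the parents and late hexaploids of cross 1 (left) and cross 2 (right). The cross 2 arrays fall off at the first and last rows, and the cross 1 arrays do not.

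The parents were compared to find the probes at which the diploid differed from the tetraploid. In cross 1, 16907 of 29706 probes differed (56.9%), with 8234 higher in the diploid and 8673 higher in the tetraploid. In cross 2, 18237 of 29648 probes differed (61.5%), with 9273 higher in the diploid and 8964 higher in the tetraploid. Differences were large, with 14504 probes of cross 1 and 15873 of cross 2 past 2-fold and medians of 2.35 and 2.37 among the called probes on the log2 scale. These are differences of signal. How well each probe matches the sequence of either parent was not tested, so they cannot be read as differences of expression alone. The crosses shared 13403 calls of the same direction, where independent lists would share 5187.5, and 455 calls were opposite. Probe 6217 (contig whsh_allContig916) was at least 5130-fold higher in the diploid of cross 1 (adjusted p = 1.3e-15) and at least 9340-fold higher in that of cross 2 (adjusted p = 3.5e-16), and it was not well above background on any tetraploid array. Probe 26980 was at least 4440-fold higher in the cross 1 diploid (adjusted p = 1.7e-21), and probe 10314 at least 8400-fold higher in the cross 2 diploid (adjusted p = 6.7e-20). In the other direction, probe 21703 was at least 10800-fold and probe 29193 at least 7650-fold higher in the cross 1 tetraploid (adjusted p = 4e-12 and 9e-14). In cross 2 the tetraploid led at probe 26650, with 6.43 ± 0.11 against -6.25 ± 2.19 (SD, n = 3 each, adjusted p = 1.3e-13), and at probe 26706, with 6.10 ± 0.34 against -6.51 ± 1.75 (SD, n = 3 each, adjusted p = 1.3e-15). Both of these were well above background on 1 of the 3 diploid arrays. The counts are of limma's moderated test with Benjamini-Hochberg adjustment. With a fixed effect of slide they were 18380 in cross 1 and 16801 in cross 2. With normexp background correction the share higher in the diploid became 58.9% in cross 1 and 73.2% in cross 2, against 48.7% and 50.8%. The share was 54.4% and 53.8% with quantile normalization, 59.0% and 58.6% in the deposited matrix and 59.2% and 62.4% with the stricter filter, so which parent had more higher probes depends on the processing.

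**Figure D2:**
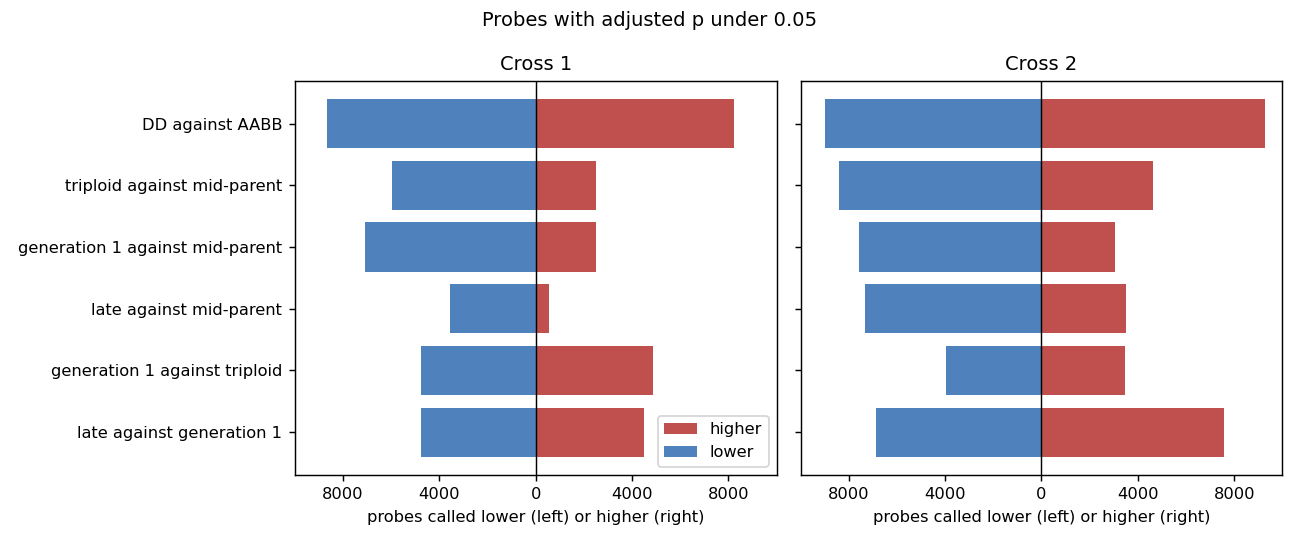
Number of probes (x axis, probes called lower to the left and higher to the right) with adjusted p under 0.05 in 6 comparisons of each cross. In cross 1 the parents differ at 16907 probes and the late hexaploid differs from the mid-parent at 4105.

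The triploid was compared with the mid-parent, the mean of the parents' linear levels, which is what an equal additive mixture of parental RNA would give. In cross 1, 8471 of 29705 probes differed (28.5%), 5966 below the mid-parent and the rest above it. In cross 2, 13030 of 29647 probes differed (44.0%), 4623 above and 8407 below. Probe 15529 (contig wheat0130Contig7559) was at least 34.5-fold above the mid-parent in cross 1 (adjusted p = 3.9e-06) and at least 137-fold above it in cross 2 (adjusted p = 3.7e-07). Its cross 1 call was lost with normexp (log2 difference 2.18, adjusted p = 0.0974). Probe 12249 was at least 67.8-fold below the mid-parent in cross 1 (adjusted p = 1.5e-08) and at least 82.3-fold below it in cross 2 (adjusted p = 4.2e-09), since it was well above background on all arrays of both diploids and on none of either triploid. Probe 19240 (contig wheat0130Contig1328) stood at -2.03 ± 0.01 in the cross 2 triploid (SD, n = 2), against 5.59 ± 0.44 in the tetraploid and 3.87 ± 0.25 in the diploid (SD, n = 3 each), which was 128-fold below the mid-parent (adjusted p = 8.6e-12). Probe 37326 was at least 115-fold above (adjusted p = 2.3e-05) and probe 9273 at least 17.1-fold below the mid-parent in cross 1 (adjusted p = 1.5e-08). Probe 23324, in the array margin, was called above it in cross 2 (adjusted p = 3.7e-06), with 5.90 in the triploid against -2.17 in the tetraploid (1 unmarked spot) and -2.09 in the diploid. These parents lay on the slides with margin loss. The probe stood at 4.26 and 4.92 in the cross 1 parents, so the rise may come from dim parental arrays and is not read as a change in the triploid. Without C1_S0 replicate 1 the cross 1 count was 3104, and without C2_S0 replicate 2 the cross 2 count was 7623. Against the mean of the parents' log2 levels the direction turned, with 60.9% of calls above it in cross 1 and 60.3% in cross 2. Above the linear mid-parent the shares were 29.6% and 35.5%. The mean of the log2 levels is never above the linear mid-parent, so this rise is built in. Quantile normalization gave 19.5% and 23.3% above the linear mid-parent. Moving each hybrid array so that probes alike in both parents had a median difference of 0, a setting chosen after the data were seen, gave 61.4% and 63.8%. With normexp the counts were 2706 and 6633, and its shares above were 20.8% and 20.9%. The deposited matrix gave 22.0% and 25.3% and the stricter filter 21.8% and 18.8%.

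The hexaploids were set against the same mid-parent. At generation 1, 9604 probes differed in cross 1 (2509 above and 7095 below) and 10611 in cross 2 (3031 above and 7580 below). In the late hexaploid the numbers were 4105 in cross 1 (532 above and 3573 below) and 10845 in cross 2 (3510 above and 7335 below). The late hexaploid of cross 1 differed at 13.8% of probes and that of cross 2 at 36.6%, and this contrast between crosses was not tested. The cross 2 late arrays had the margin loss and the low intensities given above. Among interior probes, chosen after the data were seen, 30.8% differed in the late hexaploid of cross 2 and 50.1% of these were above the mid-parent, against 32.4% above over all probes. Margin loss raises the scaled level of interior probes, so this share is not free of it. A fixed effect of slide gave 7097 probes in the late hexaploid of cross 2 and 4050 in that of cross 1. The cross 1 late count was 1454 without C1_S14 replicate 2, 2268 without C1_DD replicate 1 and 2510 without C1_DD replicate 2. It was 1112 with 2:1 weights for the tetraploid and the diploid, 8212 against the log2 mid-parent, 7523 with quantile normalization, 28 with normexp and 2012 with the hybrid arrays moved as above. With normexp the late count of cross 2 was 1807 and the generation 1 counts were 1584 and 2782. Against the log2 mid-parent, calls above made up 59.7% and 60.4% at generation 1 and 69.2% and 60.9% in the late stage of crosses 1 and 2, against 26.1%, 28.6%, 13.0% and 32.4%. The moved arrays gave 39.0% and 49.7% at generation 1 and 38.9% and 44.8% in the late stage. Quantile normalization gave 16.2% and 18% at generation 1 and 7.3% and 21.5% in the late stage. Normexp gave 14% and 24.8% at generation 1 and 28.6% and 17.1% in the late stage. The deposited matrix and the stricter filter both gave 6.7% in the late stage of cross 1, and no filter gave 46% in that of cross 2. At generation 1 of cross 2 the share was 18.3% with the stricter filter and 17.9% among interior probes.

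Chromosome doubling was examined as generation 1 hexaploid against triploid. In cross 1, 9622 probes differed, 4851 higher and 4771 lower in the hexaploid. In cross 2, 7389 differed, 3445 higher and 3944 lower. The crosses shared 4241 calls of the same direction, where independent lists would share 1196, and 108 calls were opposite. Probe 19240 was 158-fold higher after doubling in cross 1 (5.00 ± 0.28, n = 3, against -2.30 ± 0.31, n = 2, SD, adjusted p = 1.8e-11) and 343-fold higher in cross 2 (6.39 ± 0.32, n = 3, against -2.03 ± 0.01, n = 2, SD, adjusted p = 4.6e-13). Probe 14580 was at least 53.5-fold higher in cross 1 (adjusted p = 4.8e-05). Probe 5164, a margin probe, stood at 1.57 ± 0.98 in the cross 2 hexaploid (SD, n = 3) against -9.08 and -3.13 on the triploid arrays (adjusted p = 0.00015), of which only the latter was well above background. Lower after doubling were probes 11417 and 4076 in cross 1, by at least 77.6-fold and 50.5-fold (adjusted p = 0.00071 and 9.1e-06). The call of probe 11417 was lost with normexp (log2 difference -3.35, adjusted p = 0.107). In cross 2, probes 15326 and 15529 were lower by at least 175-fold and 150-fold (adjusted p = 0.00024 and 1.8e-07). Each of the 4 groups compared lay on 1 slide of its own, so slide and stage cannot be told apart here. Both generation 1 groups were scanned on the same day. The median local background was 59 to 68 on the triploid arrays of both crosses, against 48 to 49 on the generation 1 arrays. The crosses are thus not technically independent here, and whether this adds to the shared calls was not tested. A random effect of slide gave 7068 and 4924 calls, with normexp 2556 and 1728, and normexp put 65.5% of the cross 1 calls higher, against 50.4%. In cross 2 the direction turned, with 52.2% of calls higher with quantile normalization, 50.8% with normexp, 54.6% in the deposited matrix, 58.4% without a filter and 60.2% with the stricter filter, against 46.6%. The moved hybrid arrays gave 36.1% higher in cross 1 and 30% in cross 2. Cross 1 gave 57.3% with the stricter filter and 47.4% among interior probes, so no direction of the change is settled for either cross. Without C1_S0 replicate 1 the cross 1 count was 2816, and without C2_S0 replicate 1 or 2 the cross 2 count was 3930 or 2886.

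Selfing was examined as late hexaploid against generation 1. In cross 1, 9227 probes differed, 4476 higher and 4751 lower after selfing. In cross 2, 14436 differed, 7561 higher and 6875 lower. Probe 11417 (contig wheat0130Contig12787) was at least 406-fold higher in the late hexaploid of cross 1 (adjusted p = 7.2e-05) and at least 245-fold higher in that of cross 2 (adjusted p = 1e-05). Probe 15326 (contig wheat0130Contig5277) was at least 270-fold higher in cross 1 (adjusted p = 1e-04) and at least 697-fold higher in cross 2 (adjusted p = 2.3e-06). Neither was well above background on any generation 1 array. Both were also higher in the triploids than at generation 1. The folds were at least 77.6 and 63.2 for probe 11417 and at least 46.8 and 175 for probe 15326, in crosses 1 and 2. The generation 1 groups thus stand apart at these probes, and a rise with selfing is not shown. Lower after selfing in cross 1 were probe 1816, a margin probe, by at least 43.0-fold (adjusted p = 0.00013) and probe 2954 by at least 12.1-fold (adjusted p = 5.8e-09). Both calls were lost with normexp (log2 differences -1.955 and -0.937, adjusted p = 0.248 and 0.439). Lower after selfing in cross 2 were probe 35494, also in the margin, by at least 183-fold (adjusted p = 2.6e-08) and probe 35692 by at least 78.9-fold (adjusted p = 2.7e-13). The crosses shared 3887 calls of the same direction, where independent lists would share 2238.8, and 673 calls were opposite. The odds ratio for being called in both crosses was 1.05, so the lists agree in direction more than in which probes were called. Generation 1 and late arrays shared no slide, and the margin loss was in the cross 2 late arrays. All generation 1 arrays of both crosses were scanned on the same day, so the crosses are not technically independent here either. Among interior probes 74.9% of the cross 2 calls were higher after selfing, against 52.4% over all probes. Interior probes kept the scaling by all probes, so the interior share carries an offset. Their median deviation was 0.14, 0.46 and 0.25 on the cross 2 late arrays, against -0.06 to -0.03 on the cross 2 generation 1 arrays. For selfing in cross 2 the stricter filter gave 61.6% and the moved arrays 46.7%. In cross 1 the share higher was 50.6% with quantile normalization, 51.1% with a fit per cross, 43.5% with the stricter filter and 55.2% with the moved arrays, against 48.5%. Without C1_S14 replicate 2 the cross 1 count was 5283, and with normexp the counts were 792 and 4496.

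**Figure D3:**
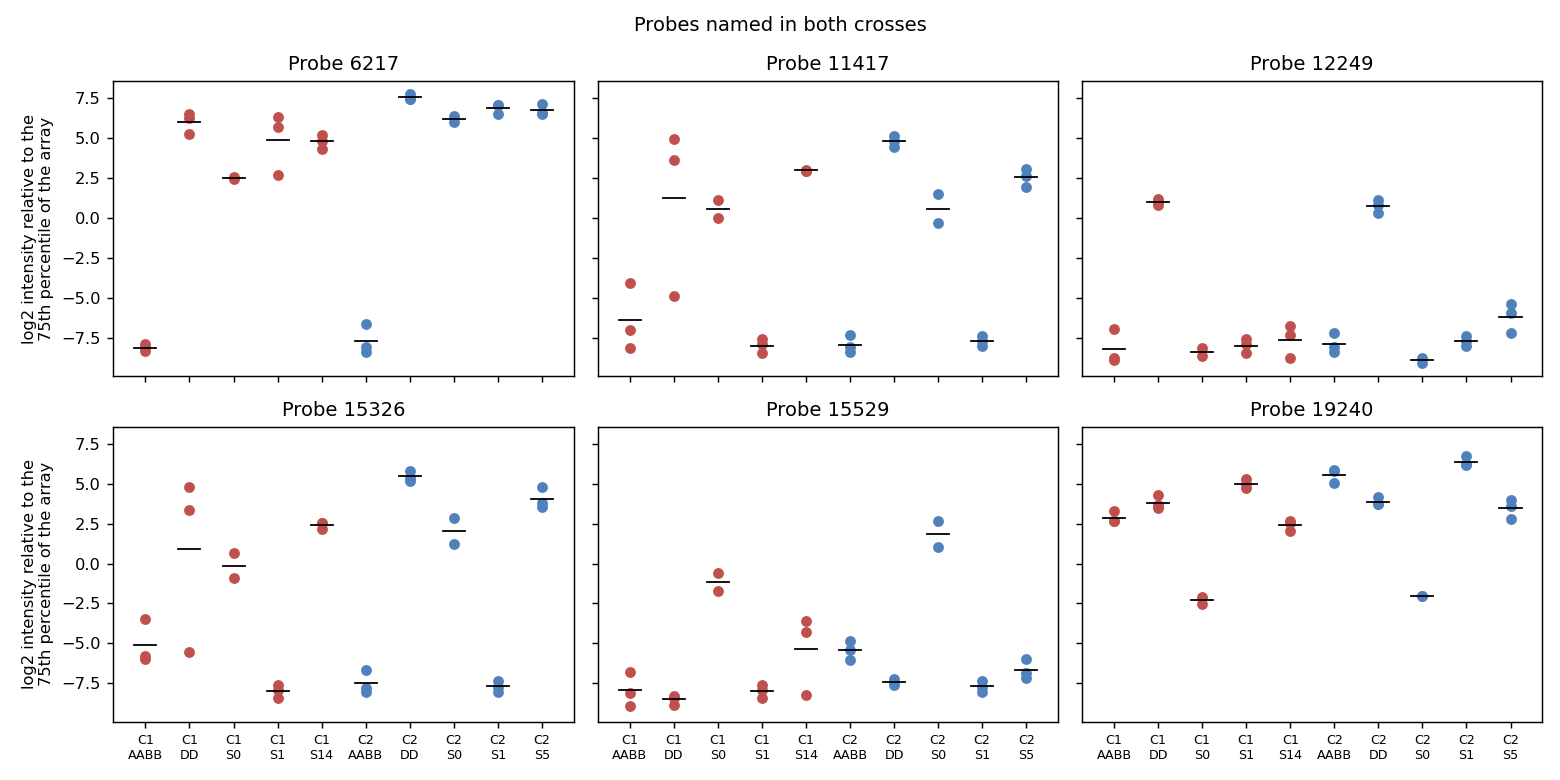
Log2 intensity relative to the 75th percentile of each array (y axis) in the 10 groups (x axis), for the 6 probes named in comparisons of both crosses, a selection made after their values were seen, with 1 point per array, red for cross 1 and blue for cross 2, and a black line at the group mean. Probe 19240 is at -2.30 and -2.03 in the triploids, and probes 11417 and 15326 are at -8.00 and -7.71 in the generation 1 hexaploids.

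Expression outside the parental range was counted where a hybrid differed from both parents in the same direction. In cross 1 this held for 2774 probes in the triploid (1016 above and 1758 below both parents), 2790 at generation 1 (847 and 1943) and 421 in the late hexaploid (144 and 277). In cross 2 it held for 5253 probes in the triploid (2434 and 2819), 2670 at generation 1 (1070 and 1600) and 3115 in the late hexaploid (846 and 2269). A fixed effect of slide gave 1958 probes in the late stage of cross 2. The order of generation 1 and late hexaploid in cross 2 turned with the stricter filter (1985 and 1820), with the local surface taken off (2450 and 2426) and among interior probes (1445 and 1039), the last 2 chosen after the data were seen. Without C2_S5 replicate 2 the late count was 2084, from 2 late arrays. The generation 1 count of 2670 came from 3 arrays, so these 2 counts do not show whether the order depends on that array. Among interior probes 6.6% lay outside the range in the late stage of cross 2, against 10.5% over all probes, and 9.2% against 9.0% at generation 1. The late hexaploid shared its slides with the parents, and the triploid and generation 1 did not. In the late stage of cross 1 the count was 168 or 263 without C1_AABB replicate 1 or 2, and 157 or 1008 without C1_S14 replicate 2 or 3. It was 1076 with quantile normalization and 271 with the hybrid arrays moved onto probes alike in the parents. The triploid count was 1121 without C1_S0 replicate 1 in cross 1, and 3493 or 2817 without C2_S0 replicate 1 or 2 in cross 2. The generation 1 count of cross 2 was 1767 without C2_S1 replicate 1. With normexp the counts in the order above were 833, 317, 36, 1953, 632 and 690.

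Where the parents differed, the hybrids were more often at the tetraploid's level than at the diploid's. A probe was counted at a parent's level where the hybrid differed from the other parent and was not called different from this one, which does not show that the levels were equal. In cross 1, of the 16907 probes that differed between parents, 7932 were at the tetraploid level and 2481 at the diploid level in the triploid, 7366 and 2561 at generation 1, and 9110 and 1050 in the late hexaploid. Of the 18237 such probes in cross 2, 7638 were at the tetraploid level and 2679 at the diploid level in the triploid, 8664 and 2227 at generation 1, and 7367 and 2955 in the late hexaploid. At each stage of both crosses the larger part of the tetraploid-level probes were higher in the tetraploid than in the diploid parent. In the triploids these were 4880, against 3052 higher in the diploid, in cross 1, and 4342 against 3296 in cross 2. Whether unequal RNA amounts of the parents give the excess at the tetraploid level was not tested. Levels between the parents and different from both were found for 3646, 4832 and 4205 probes in cross 1 and for 4529, 4894 and 5249 in cross 2. The group profiles of the hybrids correlated across probes with the tetraploid parent at r of 0.861 to 0.905 and with the diploid at 0.741 to 0.770, and probes are not independent replicates. The diploid-level count in the late hexaploid of cross 1 was 580 without C1_AABB replicate 1. With normexp it was 714, and the tetraploid-level count stayed the larger at each stage of both crosses, at 3665 against 2867 in the late stage of cross 2.

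The 2 crosses were compared at each stage. The tetraploid parents differed at 8927 probes, 3959 higher and 4968 lower in cross 2, and the diploid parents at 10205, 5544 higher and 4661 lower. The triploids differed at 2890 probes (1522 higher and 1368 lower in cross 2) and the generation 1 hexaploids at 2868 (1418 and 1450). The generation 1 arrays of both crosses were scanned on the same day on different slides, and those of the parents and the triploids on different days. The deviation from the mid-parent itself differed between crosses at 2522 probes in the triploid and at 2152 at generation 1. With a random effect of slide these last counts were 1517 and 616, and the generation 1 hexaploids differed at 1867. The diploid parents' share higher in cross 2 was 42.4% with quantile normalization and 19.8% with normexp, against 54.3%. The difference of non-additivity had 85.2% of triploid and 93.0% of generation 1 calls higher in cross 2 with normexp, against 54.6% and 55.1%, on 210 and 100 calls. The triploid and generation 1 shares turned to 43.5% and 45.7% in the deposited matrix and to 34.3% and 36.9% with the stricter filter. They were 44.2% and 45.9% with the local surface taken off and 36.7% and 35.7% among interior probes, but 68.4% and 71.2% with the moved hybrid arrays, all chosen after the data were seen. No filter gave 49.7% in the triploid. The parents' shares higher in cross 2 among interior probes were 55.1% for the tetraploids and 64.9% for the diploids, against 44.3% and 54.3% over all probes. Margin loss raises the scaled interior of the cross 2 parental arrays, so these shares carry it. For the tetraploids the share was also 50.9% with quantile normalization, 50.5% in the deposited matrix and 59.4% with the stricter filter. For the triploids (52.7%) it was 49.5% with quantile normalization. For the generation 1 hexaploids (49.4%) it was 56.5% with the stricter filter and 40.4% with normexp. The moved arrays gave 61.8% and 60.8% for these 2 hybrid comparisons. Normexp gave 2467, 1253, 600 and 275 calls for the tetraploids, diploids, triploids and generation 1 hexaploids. The triploid comparison gave 1920 or 1682 calls without C2_S0 replicate 1 or 2. Its difference of non-additivity gave 1442, 1101 or 799 without C1_S0 replicate 1, C2_S0 replicate 1 or C2_S0 replicate 2. At generation 1 that difference gave 1361, 1259 or 1326 without C1_S1 replicate 1, 2 or 3, and 835 or 1012 without C2_S1 replicate 1 or 2.

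Non-additive calls were shared between crosses and between stages. Of the same direction in both crosses were 5345 calls in the triploid, where independent lists would share 2078.3 summed over both directions, 4792 at generation 1 (2066.4) and 1719 in the late hexaploid (945.1). Within cross 1, the triploid shared 2674 calls with generation 1 (1636.5 for independent lists) and 2251 with the late hexaploid (762.4). Within cross 2 these numbers were 6105 (2616.9) and 3132 (2622.1). Opposite calls numbered 245, 166 and 165 between crosses, 580 and 41 in cross 1 and 471 and 1780 in cross 2. Of the probes called in both the triploid and the late hexaploid of cross 2, 63.8% had the same direction, with an odds ratio of 1.1 for being called in both. Stages of a cross were set against the same parental arrays, and hybrids simulated without any effect shared 0 calls in the mean of 20 simulations. With every simulated hybrid at its mid-parent, almost no call can pass the adjusted threshold. That 0 was therefore set in advance and is no baseline for the shared counts. The covariance of the deviations of triploid and generation 1 was 0.202 in cross 1 and 0.599 in cross 2, against 0.060 simulated. For triploid and late hexaploid it was 0.370 and 0.164, against 0.060 and 0.059. The correlations did not all exceed the simulated ones. They were 0.217 and 0.470 for triploid and generation 1 in crosses 1 and 2, against 0.351 and 0.350, and 0.536 and 0.118 for triploid and late hexaploid, against 0.353 and 0.347. The parents could not be halved with 2 arrays in each part, so part of the excess over independent lists may come from the shared parents. The same equal weights also enter all these calls, and a wrong weight would shift probes alike at each stage and in both crosses. With 2:1 weights the late calls of cross 1 fell from 4105 to 1112, and fewer were shared with cross 2 and with the triploid. The counts between crosses in the triploid and at generation 1 stayed within 1.5 times. How much of the sharing comes from the weights was not tested. Without C1_S0 replicate 1 the shared count between crosses in the triploid was 2172, and without C1_S14 replicate 2 that in the late hexaploid was 753. Without C1_DD replicate 1 or 2 the latter was 1015 or 1059. That late count moved further, down with normexp and 2:1 weights and up with quantile normalization and the log2 mid-parent. The triploid and generation 1 counts between crosses also fell with normexp and rose with the log2 mid-parent, and the values are given with the processing. In cross 1 the triploid shared 1541 or 1718 calls with generation 1 without C1_S0 replicate 1 or 2. With the late hexaploid it shared 1231, 1398, 1051 or 877 without C1_DD replicate 1, C1_DD replicate 2, C1_S0 replicate 1 or C1_S14 replicate 2. In cross 2 it shared 2031 or 1925 with the late hexaploid without C2_S0 replicate 1 or 2.

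The level at which each parent's own transcripts appeared in the hybrids was followed with probes well above background on all arrays of a parent and on none of the other's. There were 3289 such probes of the tetraploid and 1395 of the diploid in cross 1, and 4011 and 1573 in cross 2. In the cross 1 triploid their median level, as a linear ratio to the parent that had them, was 0.658 ± 0.007 for the tetraploid's and 0.278 ± 0.004 for the diploid's probes (SD, n = 2). At generation 1 the ratios were 0.581 ± 0.012 and 0.241 ± 0.006 and in the late hexaploid 0.611 ± 0.025 and 0.258 ± 0.004 (SD, n = 3). In cross 2 they were 0.639 ± 0.024 and 0.249 ± 0.012 in the triploid (SD, n = 2), 0.629 ± 0.013 and 0.227 ± 0.004 at generation 1, and 0.630 ± 0.025 and 0.251 ± 0.031 in the late hexaploid (SD, n = 3). Probes alike in both parents stood at 0.710 to 0.929 of the parents' level on the single arrays, so the ratios are read against each other and not against 1. Choosing probes by their detection in a parent can lower the ratio by chance.

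**Figure D4:**
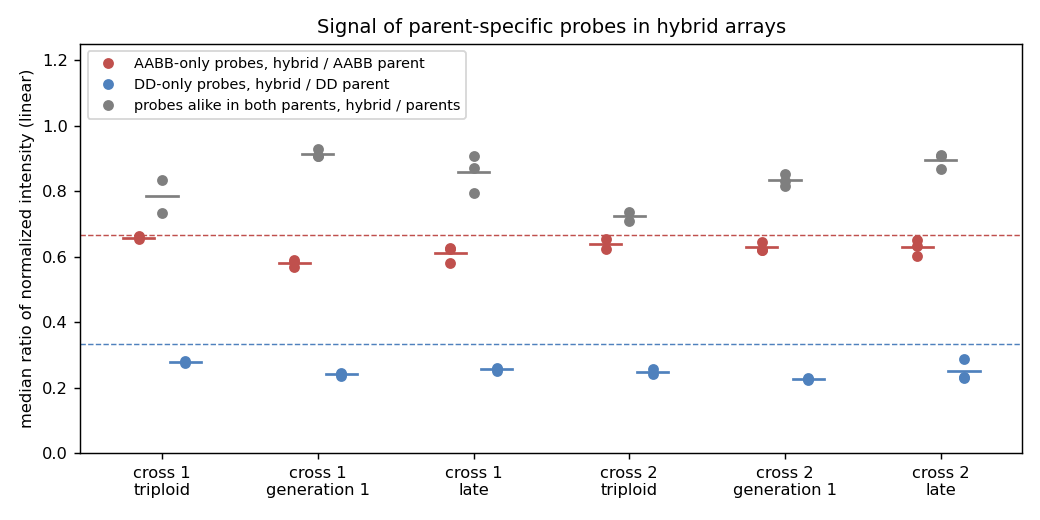
Median linear ratio of hybrid to parent (y axis) in the hybrid stages of both crosses (x axis), with 1 point per array and a line at the mean, for probes of the tetraploid alone (red), of the diploid alone (blue) and alike in both parents (grey). Dashed lines mark 2/3 (red) and 1/3 (blue), and the tetraploid's probes lie between 0.581 and 0.658 and the diploid's between 0.227 and 0.278 in the stage means.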

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

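The tests with the surface taken off, with slide as a block, with recentred hybrid arrays and with 2:1 weights were chosen or worded after at least part of their result had been seen, as were the ratios with triploid arrays left out, and the other tests before. The deviation from the mid-parent differed between crosses by a test of the difference itself, at 2522 probes in the triploid and 2152 at generation 1. In the triploid, 1544 of these probes were called against the mid-parent in cross 2 and not in cross 1, 445 the other way and 489 in both. At generation 1 the numbers were 1111, 720 and 280. With a random effect of slide the counts were 1517 and 616. For generation 1, 2 of 100 splits, the real one among them, gave at least the real count, with a highest other count of 3566. A split above the real value points to structure among the arrays. These splits exchanged arrays of the same stage between crosses, whose parents differ at 8927 and 10205 probes. They therefore do not test equal deviations from the mid-parent, and the share planned as a bound was wrong for this design, so whether chance can be excluded stays open. The triploids have 2 arrays each and were not split.

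More probes differed from the mid-parent in the triploid of cross 2 than of cross 1, 13030 against 8471, a ratio of 1.54. With 1 triploid array of each cross left out in turn the ratio ran from 1.19 to 3.21, so its size is uncertain. Margin loss on the slides of the cross 2 parents was tested by taking off the local surface. The ratio was then 1.48, and 1.14 to 2.84 with arrays left out. Dim arrays of the cross 2 parents were tested on the 14568 probes well above background on all arrays, with a ratio of 1.38, and 1.15 to 2.81 with arrays left out. Both ratios passed the bound set against these causes, but not by more than this spread, so neither cause is excluded. Each triploid lay on a slide and scan day of its own, so an effect of these cannot be told apart from a difference between the crosses. The different tetraploid and diploid parents of the crosses stay open as a biological difference, untested.

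Fewer probes lay outside the parental range in the late hexaploid of cross 1 (421) than in its triploid (2774) and generation 1 (2790). The late hexaploid shared its slides with the parents and the other stages did not. With slide as a random block the triploid count was 3.70 times the late count. As first worded, slide was to be ruled out by a ratio above 3 together with a cross 2 late count (3115) not below that of generation 1 (2670), and both were met. That wording was wrong for this design, since the block's correlation of 0.166 comes from all slides and does not bound the effect of the single slide that held each triploid, and with the surface taken off, a condition added after the values were seen, the cross 2 counts were 2426 and 2450. Among interior probes they were 1039 and 1445. Slide and stage therefore cannot be told apart for the triploid and generation 1, and a decline with selfing stays open.

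Calls below the linear mid-parent outnumbered calls above it at each hybrid stage of both crosses. The pattern depends on that choice. Against the log2 mid-parent all 6 comparisons turned, with 59.7% to 69.2% of calls above. The log2 mid-parent is never above the linear one, so the deviations rise by construction wherever the parents differ. The turn therefore does not show which direction holds. Among interior probes the late hexaploid of cross 2 did not show the excess below, with 2416 calls above and 2403 below. These probes kept the scaling by all probes of the array, and margin loss raises their scaled level. Their median deviation was 0.14, 0.46 and 0.25 on the late arrays of cross 2. With the surface taken off, 34.4% of the late calls of cross 2 were above. The interior share therefore does not show that the excess is absent. With 2:1 weights at most 35.1% of calls were above, and the late calls of cross 1 fell from 4105 to 1112. Too little weight for the tetraploid therefore does not account for the pattern alone. The test left the scaling of the hybrid arrays as it was, which could keep the share above low at either weight. Whether the weight adds to the pattern stays open. Scaling that lowers all probes of a hybrid array alike was tested by moving each hybrid array so that probes alike in both parents had a median difference of 0. Calls above then made up 38.9% to 63.8% over the 6 comparisons. As the probes alike in the parents lay below the parents' level, the move raises all probes of the hybrids and the share above rises by construction. A turned direction, as in the triploids, therefore does not show that the scaling caused the excess, and whether it did stays open. A lower level in hybrids of probes at which the parents differ stays open.

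With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and the real split is 1 of them. The highest other counts were 0 and 64 for the parents of cross 1 and cross 2, over splits that part all pairs of same-numbered arrays and those that do not, where the real counts were 16907 and 18237, and 18 and 8 for selfing, where they were 9227 and 14436. Between crosses they were 36 for the tetraploids (8927), 9 for the diploids (10205) and 1 for the generation 1 hexaploids (2868). The real split is also 1 of each 100 and is counted in the numbers that follow. For generation 1 against the mid-parent, 1 of 100 splits gave as many probes in cross 1 (9604, highest other 8128) and 4 in cross 2 (10611, highest other 17814). For the late hexaploid, 8 of 100 splits gave as many in cross 1 (4105, highest other 11485) and 2 in cross 2 (10845, highest other 13240). Outside the parental range, 1 of 100 splits gave as many at generation 1 of cross 1 (2790, highest other 1216), 4 in the late stage of cross 1 (421, highest other 4929), 4 at generation 1 of cross 2 (2670, highest other 14732) and 2 in the late stage of cross 2 (3115, highest other 7628). These splits mix the arrays of both parents, which differ at 56.9% and 61.5% of probes, with those of the hybrid. Counts several times the real one, some with a whole parent in the hybrid's place (3 splits for the late hexaploid of cross 1), point to that difference. The splits thus do not test non-additivity, the share planned as a bound was wrong for this design, and whether chance can be excluded stays open for these counts.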

How the results depend on the processing

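The surface taken off each array, the interior probes, the recentred hybrid arrays and the crossed numbers were chosen after the data were seen, and all other alternatives before. Of 43 counts, all stayed within 1.5 times the reported value without a probe filter, with a mean-variance trend and with the surface taken off, and so did the 37 counts that a fit per cross can give and 35 of the 39 with recentred hybrid arrays. Over interior probes 0 of 43 did, as 15647 of 29706 probes were tested. The cause was not tested for the changes below, except that interior probes, the stricter filter and the deposited matrix hold fewer probes. Normexp raised the median residual SD from 0.435 to 0.580. The median replicate SD rose in the diploids (from 0.301 to 0.751 in cross 1 and from 0.340 to 0.997 in cross 2) and in generation 1 (0.274 to 0.370) and the late hexaploid (0.351 to 0.679) of cross 1. It fell in the other 6 groups, as from 0.520 to 0.454 in the late hexaploid of cross 2. Quantile normalization moved the median over all probes from -0.25 to -0.51 for the triploid of cross 2, and normexp moved it from 0.13 to 0.90 for the parents of cross 2, and changes under them are relative to these shifts. Low signal over background limits what the late arrays of cross 2 can show. A group left with 1 array is assumed to vary like the other groups. Gene list tests and their alternatives were not run, as the probes have no gene names.

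The named probes kept their direction and their side of the threshold in 527 values under the alternatives that gave one, and 4 calls were lost, all with normexp. These were probe 15529 in the triploid of cross 1 (adjusted p = 0.0974, against 1.2e-07 to 0.00065 under its other alternatives) and probe 11417 in the doubling of cross 1 (0.107, against 0.00026 to 0.023). The others were probes 1816 and 2954 in the selfing of cross 1 (0.248, against 8e-05 to 0.00095, and 0.439, against 3.9e-09 to 2.2e-05). Their log2 differences with normexp were 2.18, -3.35, -1.955 and -0.937 in this order, all smaller than the lower bounds in the report.

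With the replicate number as a block all 43 counts stayed within 1.5 times, with 16950 probes for the parents of cross 1 and 18356 for those of cross 2. Among the pairs of groups not given with the methods, same-numbered arrays shared a slide for the diploid and the late hexaploid of cross 1, and for replicate 1 of the late hexaploid and both parents of cross 2. In such pairs of groups, every array correlated best with its own number for generation 1 and late hexaploid of cross 2 (6 of 6 arrays) and in no other such pair of groups of 3, with 5 of 6 for the diploid and the late hexaploid of cross 1. The triploids of the crosses correlated at r = -0.118 by number, and with the numbers crossed the block gave 2946 calls between them and 2701 for their difference of non-additivity.

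With normexp background correction, counts were 9230 for parents cross 1, 2706 for triploid against mid-parent cross 1, 1584 for generation 1 against mid-parent cross 1, 28 for late against mid-parent cross 1 and 2556 for chromosome doubling cross 1. Counts also were 792 for selfing cross 1, 6633 for triploid against mid-parent cross 2, 2782 for generation 1 against mid-parent cross 2, 1807 for late against mid-parent cross 2 and 1728 for chromosome doubling cross 2. Counts also were 4496 for selfing cross 2, 2467 for tetraploid parents between crosses, 1253 for diploid parents between crosses, 600 for triploids between crosses and 275 for generation 1 hexaploids between crosses. Counts also were 210 for the difference of non-additivity, triploid and 100 for the difference of non-additivity, generation 1. Counts outside the parental range were 833 in the triploid stage of cross 1, 317 in the generation 1 stage of cross 1, 36 in the late stage of cross 1, 1953 in the triploid stage of cross 2 and 632 in the generation 1 stage of cross 2. Counts outside the parental range also were 690 in the late stage of cross 2. Parental-level counts were 4525 at the AABB level in the triploid stage of cross 1, 1109 at the DD level in the triploid stage of cross 1, 3800 at the AABB level in the generation 1 stage of cross 1, 1121 at the DD level in the generation 1 stage of cross 1 and 3835 at the AABB level in the late stage of cross 1. Parental-level counts also were 1628 at the DD level in the triploid stage of cross 2, 4737 at the AABB level in the generation 1 stage of cross 2 and 3665 at the AABB level in the late stage of cross 2. Shared calls numbered 1712 between crosses in the triploid stage, 717 between crosses in the generation 1 stage, 8 between crosses in the late stage, 391 between triploid and generation 1 in cross 1 and 14 between triploid and late in cross 1. Shared calls also numbered 1445 between triploid and generation 1 in cross 2 and 393 between triploid and late in cross 2.

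With the filter for probes well above background in every group of the cross, which tested fewer probes, counts were 9851 for parents cross 1, 9126 for parents cross 2, 8250 for triploid against mid-parent cross 2, 7013 for generation 1 against mid-parent cross 2 and 5822 for late against mid-parent cross 2. Counts also were 4636 for chromosome doubling cross 2, 8212 for selfing cross 2, 4409 for tetraploid parents between crosses, 5480 for diploid parents between crosses and 882 for triploids between crosses. Counts also were 674 for generation 1 hexaploids between crosses. Outside the parental range, counts were 1841 in the generation 1 stage of cross 1, 250 in the late stage of cross 1, 3480 in the triploid stage of cross 2 and 1820 in the late stage of cross 2. At parental levels, counts were 4399 at the AABB level in the triploid stage of cross 1, 4293 at the AABB level in the generation 1 stage of cross 1, 5446 at the AABB level in the late stage of cross 1, 654 at the DD level in the late stage of cross 1 and 3757 at the AABB level in the triploid stage of cross 2. At parental levels, counts also were 1455 at the DD level in the triploid stage of cross 2, 4367 at the AABB level in the generation 1 stage of cross 2, 1274 at the DD level in the generation 1 stage of cross 2, 3620 at the AABB level in the late stage of cross 2 and 1848 at the DD level in the late stage of cross 2. Shared calls numbered 2052 between triploid and late in cross 2.

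On the deposited matrix, which holds fewer probes, counts were 9429 for parents cross 1, 11185 for parents cross 2, 5441 for tetraploid parents between crosses, 6598 for diploid parents between crosses and 1017 for triploids between crosses. Counts also were 892 for generation 1 hexaploids between crosses. Counts outside the parental range were 255 in the late stage of cross 1. Parental-level counts were 4212 at the AABB level in the triploid stage of cross 1, 4048 at the AABB level in the generation 1 stage of cross 1, 5210 at the AABB level in the late stage of cross 1, 619 at the DD level in the late stage of cross 1 and 4679 at the AABB level in the triploid stage of cross 2. Parental-level counts also were 1768 at the DD level in the triploid stage of cross 2, 5427 at the AABB level in the generation 1 stage of cross 2 and 4493 at the AABB level in the late stage of cross 2.

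Against the mean of the log2 levels, counts were 8212 for late against mid-parent cross 1, 3821 for the difference of non-additivity, triploid and 4223 for the difference of non-additivity, generation 1. Shared calls numbered 8387 between crosses in the triploid stage, 7506 between crosses in the generation 1 stage, 4806 between crosses in the late stage, 5993 between triploid and generation 1 in cross 1 and 6059 between triploid and late in cross 1. Shared calls also numbered 5976 between triploid and late in cross 2.

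With 2:1 weights, counts were 1112 for late against mid-parent cross 1. Shared calls numbered 350 between crosses in the late stage, 1584 between triploid and generation 1 in cross 1, 553 between triploid and late in cross 1 and 1945 between triploid and late in cross 2.

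With quantile normalization, counts were 7523 for late against mid-parent cross 1. Outside the parental range, counts were 1076 in the late stage of cross 1. Shared calls numbered 3529 between crosses in the late stage, 4040 between triploid and generation 1 in cross 1 and 4867 between triploid and late in cross 1.

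With a random effect of slide, counts were 4924 for chromosome doubling cross 2, 1867 for generation 1 hexaploids between crosses, 1517 for the difference of non-additivity, triploid and 616 for the difference of non-additivity, generation 1.

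With a fixed effect of slide, counts were 7097 for late against mid-parent cross 2. Outside the parental range, counts were 1958 in the late stage of cross 2.

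Over interior probes, which are fewer, counts were 9280 for parents cross 1, 4947 for triploid against mid-parent cross 1, 5738 for generation 1 against mid-parent cross 1, 2686 for late against mid-parent cross 1 and 5743 for chromosome doubling cross 1. Counts also were 5525 for selfing cross 1, 9941 for parents cross 2, 7323 for triploid against mid-parent cross 2, 6091 for generation 1 against mid-parent cross 2 and 4819 for late against mid-parent cross 2. Counts also were 4440 for chromosome doubling cross 2, 7382 for selfing cross 2, 4848 for tetraploid parents between crosses, 5511 for diploid parents between crosses and 1673 for triploids between crosses. Counts also were 1702 for generation 1 hexaploids between crosses, 1142 for the difference of non-additivity, triploid and 1042 for the difference of non-additivity, generation 1. Counts outside the parental range were 1666 in the triploid stage of cross 1, 1736 in the generation 1 stage of cross 1, 264 in the late stage of cross 1, 2882 in the triploid stage of cross 2 and 1445 in the generation 1 stage of cross 2. Counts outside the parental range also were 1039 in the late stage of cross 2. Parental-level counts were 4231 at the AABB level in the triploid stage of cross 1, 1374 at the DD level in the triploid stage of cross 1, 3847 at the AABB level in the generation 1 stage of cross 1, 1429 at the DD level in the generation 1 stage of cross 1 and 4806 at the AABB level in the late stage of cross 1. Parental-level counts also were 638 at the DD level in the late stage of cross 1, 3970 at the AABB level in the triploid stage of cross 2, 1436 at the DD level in the triploid stage of cross 2, 4565 at the AABB level in the generation 1 stage of cross 2 and 1169 at the DD level in the generation 1 stage of cross 2. Parental-level counts also were 4271 at the AABB level in the late stage of cross 2 and 1666 at the DD level in the late stage of cross 2. Shared calls numbered 3334 between crosses in the triploid stage, 3085 between crosses in the generation 1 stage, 946 between crosses in the late stage, 1676 between triploid and generation 1 in cross 1 and 1497 between triploid and late in cross 1. Shared calls also numbered 3540 between triploid and generation 1 in cross 2 and 1412 between triploid and late in cross 2.

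With the hybrid arrays recentred on probes alike in the parents, counts were 2012 for late against mid-parent cross 1. Outside the parental range, counts were 271 in the late stage of cross 1. Shared calls numbered 893 between crosses in the late stage and 993 between triploid and late in cross 1.

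With each array left out in turn, counts ran from 3104 to 8141 for triploid against mid-parent cross 1, 1454 to 4262 for late against mid-parent cross 1, 2816 to 9181 for chromosome doubling cross 1 and 5283 to 8914 for selfing cross 1. They ran from 1121 to 3041 outside the range in the triploid stage of cross 1, 157 to 1008 outside the range in the late stage of cross 1, 580 to 1248 at the DD level in the late stage of cross 1 and 7623 to 13135 for triploid against mid-parent cross 2. The range was 2886 to 5709 for chromosome doubling cross 2, 2817 to 5288 outside the range in the triploid stage of cross 2, 1767 to 2623 outside the range in the generation 1 stage of cross 2 and 1682 to 2650 for triploids between crosses. They ran from 799 to 2969 for the difference of non-additivity, triploid, 835 to 3192 for the difference of non-additivity, generation 1, 2172 to 5327 shared between crosses in the triploid stage and 753 to 2007 shared between crosses in the late stage. The range was 1541 to 2510 shared between triploid and generation 1 in cross 1, 877 to 2378 shared between triploid and late in cross 1 and 1925 to 3215 shared between triploid and late in cross 2.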

Other observations

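The tests of contribution by genome number and in equal parts were chosen before their values were seen, and the probes singled out here after. That an outcome must hold under both scalings was required after their values were seen. The tetraploid's share of the ratios of parent-specific probes, its own ratio over the sum of both, was 0.704 in the mean of the 3 hybrid stages of cross 1 and 0.724 in cross 2. RNA from both parents in equal parts predicts 0.5, and the shares argue against it in both crosses as far as the scaling between the parental arrays holds. RNA in proportion to the number of genomes predicts 2/3. Each stage of cross 1 (0.703 to 0.707) lay within 0.05 of it, the bound set for agreement, and the cross 2 stages (0.716 to 0.735) did not all do so. With quantile normalization the means were 0.749 and 0.757, which is past the bound set against the hypothesis (0.08) in both crosses. The outcome thus turned with the scaling, and the test did not decide in either cross. The shares lay past the bound set against equal parts under both scalings. Both scalings set the parental arrays to a common level, and an error in that level enters the share directly. Equal parts are therefore not excluded.

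Of 20655 probes well above background on all arrays of both cross 1 parents, 82 were not on any triploid array, 279 on no generation 1 array and 13 on no late array, and of 17418 in cross 2 the numbers were 1, 36 and 294. Of the 294, 118 lay in the margin. Of 9010 probes well above background on no parental array of cross 2, 1227 were on both triploid arrays, which were the brightest of the series, against 92 of 6653 in cross 1. Of the 1227, 234 lay in the margin, where the cross 2 parental arrays were dim. No probe was lost in all 3 stages of either cross (0 and 0), and 1 per cross was gained in all 3.

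Among 301 probes that were bright in the diploid and not detected in the tetraploid in both crosses, 1 was not well above background on any hybrid array of either cross. It is probe 12249, at 0.99 ± 0.19 and 0.75 ± 0.40 in the diploids (SD, n = 3). Of 746 such probes of the tetraploid, 0 were so.

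Probe 19240 stood apart in the triploids of both crosses, which were scanned on different days. Both triploids had a higher median local background (59 to 68) than the other groups (48 to 50.5), so a technical difference common to them is not excluded. The probe was 36.2-fold and 69.1-fold lower in the cross 1 triploid than in its tetraploid and diploid parent (adjusted p = 4.1e-11 and 5.2e-13). It was 26.4-fold lower there than in the late hexaploid (adjusted p = 9.4e-08). In cross 2 the folds were 196, 59.8 and 45.7 (adjusted p = 4.4e-14, 1.1e-12 and 1.9e-10). It was chosen for these comparisons after its values were seen. Probes 11417 and 15326 were well above background on all 3 cross 1 diploid arrays but spread widely there, with 4.98, -4.92 and 3.65 for probe 11417 and 4.83, -5.52 and 3.37 for probe 15326.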
